A study of Mus musculus with 10 samples.

How the data were processed

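RNA was measured in microglia, the resident immune cells of the brain, from adult C57BL/6 mice of 3 to 5 months that carried 2, 1 or 0 intact copies of Trem2. Trem2 encodes a lipid-sensing receptor of microglia and other myeloid cells. Per the labels' protocols, cells were isolated with magnetic beads against CD11b, an integrin subunit of myeloid cells, total RNA was extracted with a column kit, libraries were made with an amplifying cDNA kit (Ovation RNA-seq system v2), and sequencing was done on an Illumina HiSeq4000. CD11b is also carried by monocytes, neutrophils and border macrophages, so the bead step does not exclude those cells. There were 10 libraries: 4 wild type (Trem2+/+; 2 female, 2 male), 3 heterozygous (Trem2+/-; 2 female, 1 male) and 3 knockout (Trem2-/-; 1 female, 2 male). The library numbers in the labels are wild type 1, 4, 7 and 10, heterozygous 5, 8 and 11, and knockout 6, 9 and 12. From 4 onwards they run wild type, heterozygous, knockout in turn. The sources used here do not say whether such runs were prepared together. No pairing or block across genotypes was fitted. Any difference between such runs stayed in the residual spread, which may have lowered the number of genes called. The labels do not say whether a library came from 1 mouse or from a pool, so p-values measure the spread between these libraries.

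The deposited files hold RPKM (reads scaled to gene length in kilobases and to the library total) computed by the authors, 1 value per gene and library on a linear scale. STAR, HTSeq, edgeR and limma and the build mm10 are named in the submitters' processing notes; their versions, their order and the annotation are not given in the sources used here. Each file lists 24060 gene names, of which 20008 have a value above 0 in at least 1 library. In all 20008, the values of the 10 libraries were whole multiples of what 1 read is worth, within 0.0005 reads or a relative 3e-07, so whole reads could be recovered. The library totals behind the deposited RPKM were 1.0176 to 1.0262 times the recovered reads. A spreadsheet had turned 27 gene names into dates, and those genes were not used. Of the remaining names, 22735 matched the GENCODE release M21 annotation of GRCm38, the assembly that mm10 denotes, 856 matched through a synonym and 442 did not match. Coordinates are from that annotation, whose build matches the one in the submitters' notes but which may not be the annotation used by the authors.

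The design fixed before the data were examined assumed raw counts. Because the values are RPKM, a count model was not used as the main test, and the planned comparisons were run with limma 3.58.1 in R 4.3.3 instead. Values were transformed as log2(RPKM + 0.5), and genes with at least 0.5 RPKM in at least 3 libraries were kept, which left 13641 genes. All 10 libraries entered 1 linear model with genotype and sex as terms, with a mean-variance trend in the empirical Bayes step (limma-trend). The contrasts were knockout against wild type, heterozygous against wild type, knockout against heterozygous, the slope on the number of lost Trem2 copies, and heterozygous against the midpoint of wild type and knockout. P-values were adjusted by the Benjamini-Hochberg method over the 13641 genes, and a gene was called changed at an adjusted p under 0.05. All tests were two-sided. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of genes with low values. Levels are given as mean RPKM ± SD, with n = 4 for wild type and n = 3 for the other genotypes. Single quantities were also compared with an exact permutation test, whose smallest possible p is 0.0286 for 4 against 3 libraries and 0.1 for 3 against 3.

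Gene lists were fixed before the data were examined: 21 lists of microglial states, signalling and metabolism and 14 lists of markers of other cells, 35 in all. Trem2 was left out of every list. The 30 lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 90 tests of 30 lists and 3 comparisons. Camera with an estimated correlation and fry were run beside it. Under all 21 settings that kept 9 or 10 libraries of the 3 genotypes, camera with an estimated correlation called 0 lists (lowest adjusted p = 0.243). Member genes were also tested after adjustment over the list alone. The genes named were chosen by a rule that was fixed before the data were examined: Trem2 and its neighbours, up to 10 called genes in each direction with the largest fold change, and, where fewer than 5 genes were called, the 5 with the smallest p. Apart from Trem2 and its neighbours, this rule was limited to genes with an average log2 CPM of at least 1 and left out clone and predicted-gene names, microRNA and snoRNA genes and pseudogene names. For each list, up to 3 members with the highest mean expression were named. The result of 1 list member is not reported here. Other list members, and B430306N03Rik, Camp, Ltf, Chil3, Ifitm6, Mir5104 and S100a11, were named after their values had been seen. Genes near Trem2 were compared with all other tested genes by Fisher's exact test. The rule that counts genes with an unadjusted p under 0.05, and the window of 1 Mb, were chosen after the data had been seen.

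The recovered reads numbered 17.31 M to 22.1 M in libraries 1 to 8 and 36.48 M to 44.29 M in libraries 9 to 12. The deeper set holds 4 libraries: wild type 10, heterozygous 11, and knockout 9 and 12. Genotypes were also compared within each set, and the set was fitted as a covariate. Libraries 1 to 8 (3 wild type, 2 heterozygous, 1 knockout) were fitted with the sex term, which leaves 2 residual degrees of freedom. Libraries 9 to 12 (1 wild type, 1 heterozygous, 2 knockout) were fitted without it, which leaves 1, because there both knockout libraries are male and the other 2 female. A group with 1 library is assumed to vary like the others. A level of 3 reads corresponds to 0.068 to 0.173 CPM, and a floor of this kind covers counting error only. Intervals of fold changes rest on the residual spread between libraries. The 95% interval of the fold change lay within 2-fold either way for 89.1% of the tested genes in knockout against wild type, 90.2% in heterozygous against wild type and 86.6% in knockout against heterozygous.

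The pipeline was tested on simulated data with about 200 genes changed by a known fold. In knockout against wild type it recovered 22.8% of genes changed 1.5-fold (13407 genes in the step), 64.5% of genes changed 2-fold (13412 genes) and 95.9% of genes changed 4-fold (13407 genes). In heterozygous against wild type the shares were 10.6% (13410 genes), 70.2% (13405 genes) and 97% (13408 genes). In knockout against heterozygous they were 0% (13395 genes), 66.2% (13402 genes) and 93.5% (13410 genes). About 200 genes were changed at once and noise was drawn independently for each gene. The shares therefore do not carry over to data in which few genes change. In the real data, Trem2 in heterozygous against wild type (log2 -1.02, SE 0.14) had a limma adjusted p of 0.239.

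Alternatives fixed in advance were no sex term, limma-voom on the recovered reads with and without sample quality weights, no filter on low values, a filter of at least 1 CPM in 3 libraries, only the 2 genotypes compared, and leaving out each library in turn. Pseudocounts of 0.1 and 1, median-ratio scaling, the deeper libraries 9 to 12 as a covariate, and fits within each depth set were added after the data had been seen. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Whether reads were counted by strand is not given in the sources used here, so reads of overlapping or antisense genes, and of closely related genes, may not be told apart. Except where a value is said to come from fewer libraries, fits held all 10. No pair of libraries agreed within counting noise (chi-square per degree of freedom at least 16.1 within and 15.3 between genotypes), so none was treated as 1 library deposited more than once. That does not show whether libraries came from separate animals.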

Results

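Transcript levels were compared in CD11b-isolated microglia from 4 wild-type, 3 heterozygous and 3 Trem2-knockout libraries of adult mice. The study concerns whether loss of 1 Trem2 copy is enough to alter microglia, in the setting of injury and tau pathology; the libraries analysed here differ in Trem2 genotype and sex. Recovered reads per library ranged from 17.31 M to 44.29 M (M, megareads). Values above 0 were present for 16323 to 18063 genes per library, and 11482 to 11907 genes reached 1 RPKM. The 10 most abundant genes took 8.52% to 9.88% of the reads of a library. Correlations of log2 values across genes had a median of 0.973 both within genotypes (range 0.959 to 0.984) and between them, so libraries of 1 genotype were not closer to each other than to the rest. The first principal component of the 500 most variable genes (35.3% of variance) was negative in the 5 female and positive in the 5 male libraries. On the second component (20.9%), knockout library 6 stood at 13.28, against -7.58 to 4.62 in the other 9.

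Trem2 itself followed the number of intact copies. The gene lies on chromosome 17 at 48346401 to 48354147 on the plus strand of GRCm38 (ENSMUSG00000023992.14). It stood at 191 ± 31.1 RPKM in wild type (SD, n = 4), 93.9 ± 9.98 in heterozygous (SD, n = 3) and 24.5 ± 3.52 in knockout libraries (SD, n = 3). Heterozygous microglia thus held 49.2% of the wild-type level and knockout microglia 12.8%. Reads assigned to Trem2 in the knockout numbered 627, 934 and 1103 in libraries 6, 9 and 12; which part of the gene the allele removes is not given in the sources used here. The 3 genotypes did not overlap (lowest wild type 170, heterozygous 85.2 to 105, highest knockout 28.3). Trem2 fell in knockout against wild type (log2 -2.93, SE 0.14, limma adjusted p = 5.48e-06) and in knockout against heterozygous (log2 -1.91, SE 0.16, limma adjusted p = 0.00128). Exact permutation tests gave p = 0.0286 for knockout against wild type, p = 0.0286 for heterozygous against wild type and p = 0.1 for knockout against heterozygous, each the smallest that its number of libraries allows.

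**Figure D1:**
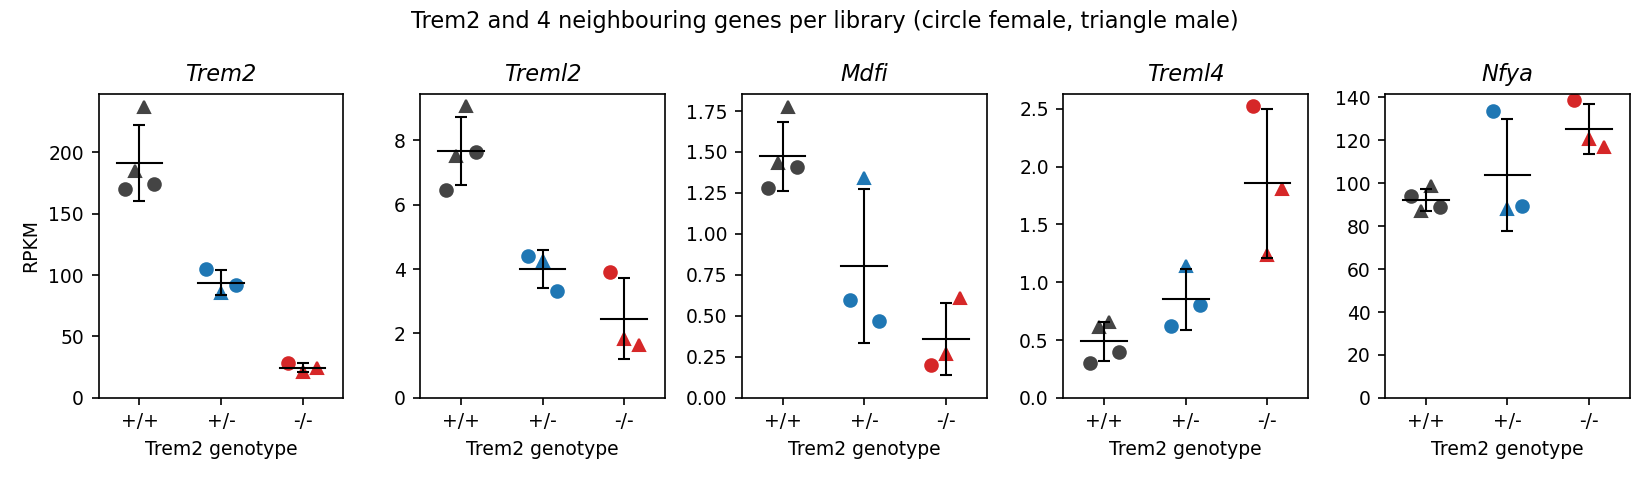
RPKM of Trem2 and 4 neighbouring genes in each library by Trem2 genotype; circles are female and triangles male libraries, horizontal lines are means and bars are SD (n = 4, 3 and 3). Trem2 stood at 191, 93.9 and 24.5 RPKM in wild-type, heterozygous and knockout libraries, and Treml2 at 7.67, 3.99 and 2.46.

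Knockout against wild type asks what complete loss of the receptor does to these cells. Trem2 was the 1 gene of 13641 that changed, by limma at an adjusted p under 0.05. With 0 genes rising, 453 genes had a positive and 247 a negative fold change at an unadjusted p under 0.05, 700 in all where 682 are expected by chance. Several genes beside Trem2 on chromosome 17 were among those with the smallest p-values of the remainder. Treml2, a TREM-family receptor of lymphoid and myeloid cells, was at 32.1% of wild type (log2 -1.51, SE 0.24, limma adjusted p = 0.434). Mdfi, an inhibitor of myogenic transcription factors, was at 24.3% (log2 -1.30, SE 0.23, limma adjusted p = 0.632), and Unc5cl, a death-domain protein, at 446% (log2 1.22, SE 0.25, limma adjusted p = 0.914) from a wild-type level of 0.287 ± 0.187 RPKM. Away from that region the rule named Mmp9, a gelatinase stored in neutrophil granules (log2 1.62, SE 0.29), and Dgat1, an enzyme of triglyceride synthesis (9.04 ± 1.60 RPKM in wild type, 13.7 ± 1.26 in knockout; log2 0.62, SE 0.13), and neither passed by limma on log2(RPKM + 0.5). Mmp9 was at 7.01 RPKM in knockout library 6, at 2.43 and 2.83 in the other 2 knockout libraries and at 0.584 to 1.39 in wild type. Leaving out knockout library 6, 3 genes fell (Trem2, Treml2 and the microRNA gene Mir5104). limma-voom on recovered reads called 2 (Trem2 and Treml2), and 17 with the deeper libraries as a covariate, of which 15 rose, including the granule genes Camp and Ltf, Mmp9 (log2 2.25, adjusted p = 0.00314) and Unc5cl (log2 2.43, adjusted p = 0.0447).

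The TREM cluster and its neighbours, a list of 12 genes fixed before the data were examined, changed in both directions in the knockout. Of its 10 measured genes, 0 passed over all genes by limma and 7 had an unadjusted p under 0.05; adjusted over the list alone, 4 rose and 2 fell. The 4 that rose were Treml4 (376% of wild type, log2 1.21), Unc5cl (446%), Treml1, a TREM-like receptor known from platelets (172%, log2 0.72), and Nfya, a subunit of the NF-Y transcription factor (135%, log2 0.46; 92.3 ± 5.21 RPKM in wild type, 125 ± 11.7 in knockout). The 2 that fell were Treml2 and Mdfi. Limma p-values adjusted over the list alone were 0.000636 for Treml2, 0.000811 for Mdfi, 0.00167 for Unc5cl, 0.00176 for Treml4, 0.0112 for Nfya and 0.0308 for Treml1. Without knockout library 6 the calls of Nfya and Treml1 ended, which left 2 genes that rose and 2 that fell. Nfya and Treml1 stood at log2 0.42 and 0.43 there, against 0.46 and 0.72 with all libraries. Treml4 and Unc5cl kept their calls at log2 0.815 and 1.095, against 1.21 and 1.22. The percentages of Treml4 and Unc5cl rest on low wild-type levels (0.492 ± 0.169 and 0.287 ± 0.187 RPKM). The call of Treml1 also ended without wild-type library 1 or 10 or without the filter on low values. In contrast, 6 genes rose with sample quality weights or with the depth covariate, where Apobec2 and Trem1 were added. Apobec2 was also added without wild-type library 1, and Trem3 without the filter. Apobec2, of the cytidine deaminase family, was at 138% of wild type (log2 0.46, SE 0.20). Trem1, an amplifier of inflammatory signals in neutrophils and monocytes, was at 5.73 RPKM in knockout library 6 and at 0.602 to 1.48 in the other knockout and the wild-type libraries (log2 0.89, SE 0.45). Foxp4 (log2 -0.03, SE 0.28) and Oard1, which removes ADP-ribose from proteins (log2 0.08, SE 0.15), were near the wild-type level. Trem3 and Tspo2 lay below the filter. As a set, the list had a median of 0.46, a mean of 0.22 and a camera adjusted p = 0.111.

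Of the 27 other genes tested within 1 Mb of Trem2, 12 had an unadjusted p under 0.05 in the knockout, 9 of them higher and 3 lower. These 12 include the 7 list members with such a p given above. Most of the remainder stood under 1 RPKM in wild type (0.293 to 0.988). The rule and window were chosen after the values had been seen. With them the share was 44.4% against 5.05% of genes elsewhere (Fisher's exact test, p = 2.57e-09), which in part restates those list members. Within 10 Mb the share was 16.6% (24 of 145 genes, against 5% elsewhere; Fisher's exact test, p = 3.3e-07). Counting genes called over all genes, as planned, Trem2 itself was the 1 gene called in the 10 Mb window and 0 were called elsewhere. B430306N03Rik, a gene of the same receptor cluster 28.7 kb from Trem2, was at 4.73 ± 1.08 RPKM in wild type and 7.56 ± 0.88 in knockout (log2 0.70, SE 0.14, limma adjusted p = 0.903). In the fit without knockout library 6, 8 of the 27 genes within 1 Mb had an unadjusted p under 0.05 (29.6% against 6.33% elsewhere; Fisher's exact test, p = 0.000197).

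**Figure D2:**
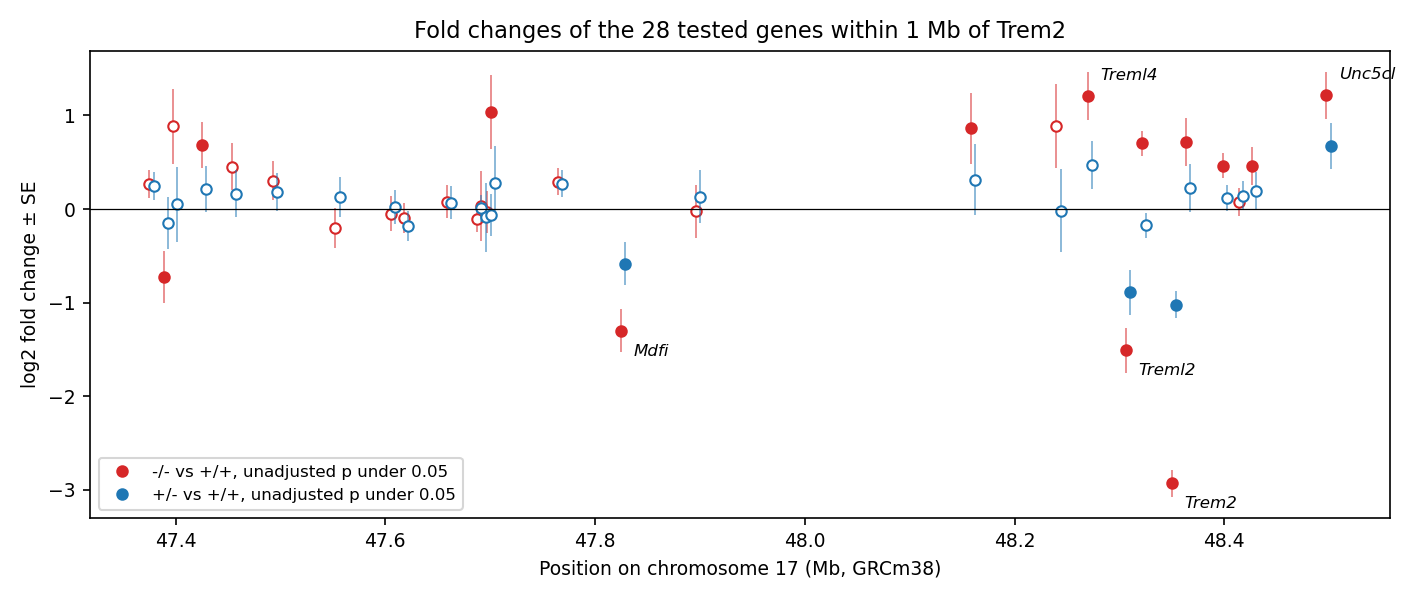
Log2 fold change ± SE against wild type of the 28 tested genes within 1 Mb of Trem2, by position on chromosome 17 (Mb, GRCm38); red points are knockout and blue points, drawn slightly to the right, heterozygous libraries, filled where the unadjusted p is under 0.05. Filled red points number 13 with Trem2, from -2.93 for Trem2 to 1.22 for Unc5cl.

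Among microglial gene groups, the programme known from disease-associated microglia was called lower in the knockout by camera at the preset correlation. Of its 28 measured genes 18 had a negative and 10 a positive fold change (median -0.13, camera adjusted p = 1.32e-05, and adjusted p = 0.631 with an estimated correlation). The 2 genes that fell when adjusted over the list alone were Lpl, a lipase that releases fatty acids from lipoproteins (log2 -0.59, SE 0.16), and Timp2, an inhibitor of matrix metalloproteinases (log2 -0.41, SE 0.11); 0 passed over all genes by limma, and 8 had an unadjusted p under 0.05. Itgax (log2 -0.54), Csf1 (log2 -0.55) and the phagocytic receptor Axl (log2 -0.49, and -0.26 without knockout library 6) were among those 8. Without that library Clec7a moved from log2 -0.67 to -0.20 and Apoe from 0.01 to 0.43. The most abundant members of the list gave log2 -0.21 for B2m, 0.01 for Ctsd and -0.10 for Fth1. The list had a median of -0.08 without knockout library 6 (camera adjusted p = 0.141) and of -0.09 without wild-type library 7 (0.000193). The calls of Lpl and Timp2 both ended without any 1 of wild-type libraries 1, 4, 7 and 10, heterozygous library 8 and knockout libraries 6 and 9, and that of Timp2 without knockout library 12. Without wild-type library 4, 3 other members passed (Ank, Axl and Csf1). Both calls also ended without the sex term. In contrast, 4 members fell without the filter or with median-ratio scaling, 6 with sample quality weights, and 7 with the depth covariate (9 by limma-voom). The inflammatory and NF-kB list was also lower (22 of 32 negative, median -0.12; camera adjusted p = 0.00066, and adjusted p = 0.675 with an estimated correlation). Its median was -0.06 without knockout library 6 (camera adjusted p = 0.141) and -0.07 without wild-type library 10 (0.0324). Its members Gpr84, a receptor for medium-chain fatty acids, Cxcl16 and Nfkbia, the NF-kB inhibitor, stood at log2 -0.44, -0.41 and -0.42. Small negative shifts were called for lysosomal genes (median -0.05; camera adjusted p = 0.0446, and adjusted p = 0.78 with an estimated correlation) and survival genes (median -0.05; camera adjusted p = 0.0446, and adjusted p = 0.631 with an estimated correlation). The lysosomal call ended without any 1 of wild-type libraries 1, 7 and 10, heterozygous library 8 and knockout library 6 (adjusted p from 0.0637 to 0.84; median -0.009 without knockout library 6) or with either other filter (0.0543 and 0.0924), and the median was -0.074 without wild-type library 4 or knockout library 9. The survival call ended without wild-type libraries 4 and 10, heterozygous library 8 and knockout libraries 6 and 9 (adjusted p from 0.0634 to 0.29; median 0.003 without knockout library 9), and the median was -0.09 without wild-type library 7. It also ended by limma-voom, with sample quality weights, without the filter and with the depth covariate (adjusted p from 0.0591 to 0.0884). Their most abundant genes were close to wild type, with log2 0.01 for Ctsd and 0.03 for Csf1r.

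In the opposite direction, cell cycle genes were higher in the knockout (21 of 24 positive, median 0.33; camera adjusted p = 6.96e-05, and adjusted p = 0.631 with an estimated correlation), with the proliferation marker Mki67 at log2 0.69 (SE 0.24; 0.25 without knockout library 6) and the ubiquitin-conjugating enzyme Ube2c at log2 1.18 (SE 0.38), while Pcna was at -0.19. Interferon-stimulated genes were also higher (26 of 32 positive, median 0.13; camera adjusted p = 0.0249, and adjusted p = 0.835 with an estimated correlation), with Ifitm3, a restriction factor for viral entry, at log2 0.53 (SE 0.15). Both calls ended without knockout library 6 (adjusted p = 0.325 and 0.562), where the cell cycle median was 0.22 and the direction of the camera test turned for the interferon list (median 0.002). The interferon call also ended without wild-type library 1 (adjusted p = 0.576, median 0.055) or 7 (0.0952), without the sex term (0.303), by limma-voom (0.0619) and with sample quality weights (0.0552).

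The remaining gene lists were not called with all 10 libraries. Homeostatic microglial genes had a median of 0.03, with the purinergic receptor P2ry12 (1966 ± 272 RPKM in wild type) and Sparc at log2 0.08 and -0.04. Medians were 0.04 for signalling through the adaptor DAP12 (Tyrobp log2 0.13), 0.06 for lipid uptake and efflux (Apoe 0.01), 0.10 for cholesterol synthesis (Insig1 -0.07), -0.03 for complement and phagocytosis (C1qc -0.16), 0.07 for injury sensing and motility (Actb 0.08) and 0.04 for antigen presentation (Cd74 -0.12). They were -0.04 for immediate early genes (Egr1 -0.20), 0.03 for oxidative phosphorylation (Atp5b -0.03), 0.08 for glycolysis (Slc2a1 0.13), 0.03 for ribosomal proteins (Rpl4 -0.15), -0.04 for autophagy (Sqstm1 -0.17), -0.02 for endoplasmic reticulum stress (Hspa5 -0.09) and 0.01 for mouse orthologues of Alzheimer risk genes (Cd33 -0.10). Immediate early genes were called lower without wild-type library 4 or 7 or knockout library 12, with sample quality weights, median-ratio scaling or the depth covariate (adjusted p from 0.000166 to 0.0478). The TREM cluster list was called higher with the depth covariate (0.0128, and 0.00938 by limma-voom). The lowest camera adjusted p among uncalled lists was 0.0616, and in 5 of the 30 lists, none of them called, the sign of the median differed from the direction of the camera test; the sign of the mean did so in 5. With an estimated correlation camera called 0 lists (lowest adjusted p = 0.631, with 2 lists at an unadjusted p under 0.05), and fry also called 0 (lowest adjusted p = 0.778, with 2 lists at an unadjusted p under 0.05).

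**Figure D3:**
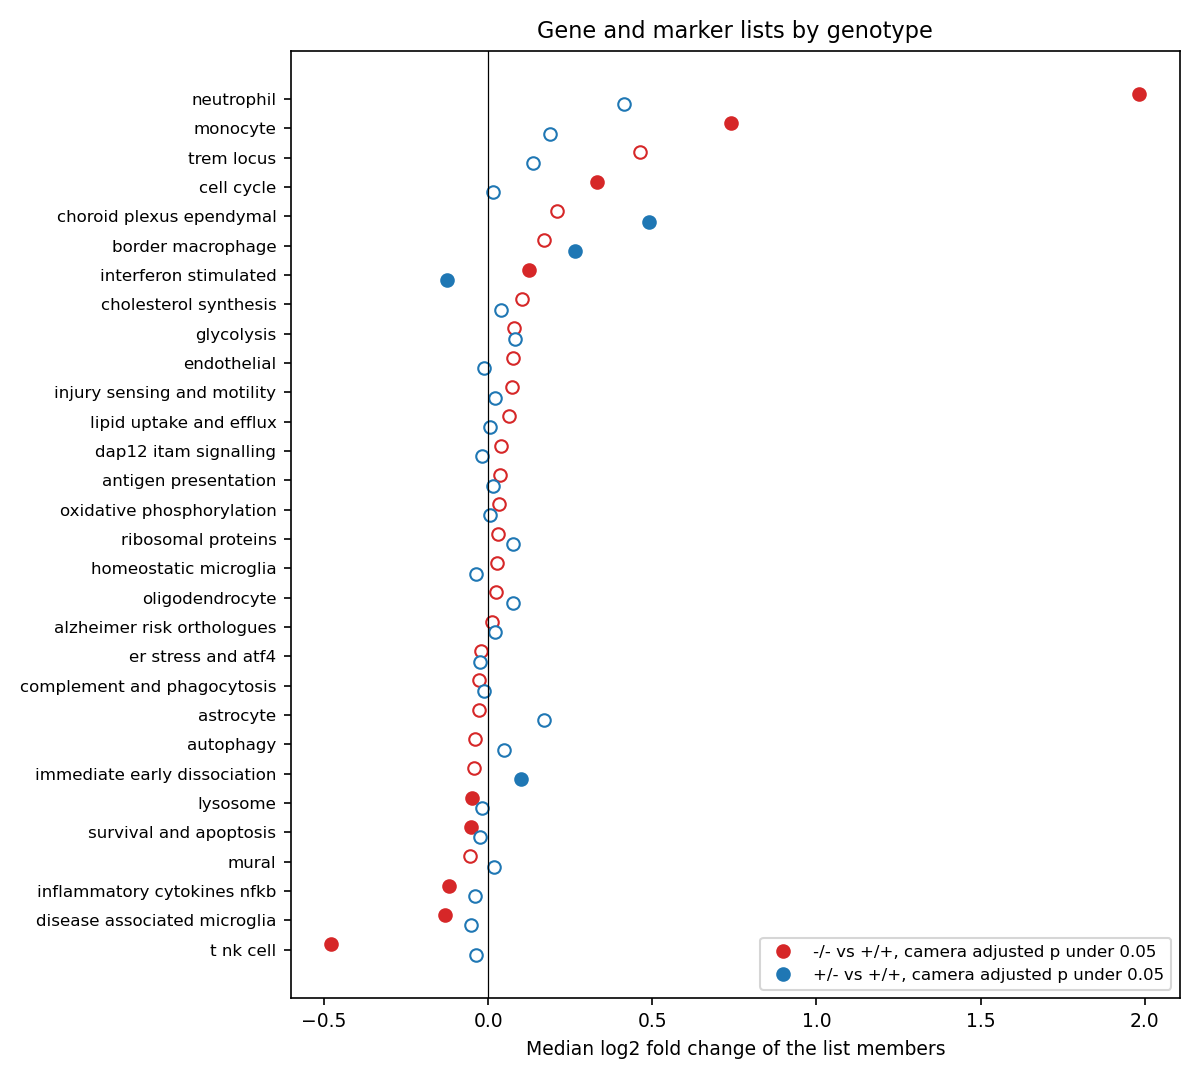
Median log2 fold change of the members of the 30 tested gene and marker lists in knockout (red) and heterozygous (blue) against wild type, filled where the camera adjusted p is under 0.05. Filled red points number 9, from -0.48 for T and NK cell markers to 1.98 for neutrophil markers, and filled blue points 4.

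Of the 30 lists, neutrophil and monocyte markers had the largest medians in the knockout, and knockout library 6 held the highest level of both. Neutrophil markers were higher in the knockout as a list (11 of 11 positive, median 1.98; camera adjusted p = 5.68e-13, and adjusted p = 0.631 with an estimated correlation). By limma, 0 passed over all genes, 9 had an unadjusted p under 0.05 and 9 rose when adjusted over the list alone, among them Ngp (log2 2.20), Camp (2.42) and the calprotectin subunits S100a9 (2.14) and S100a8 (1.72). Csf3r, a receptor that is abundant in all libraries, was at 132 ± 8.79 RPKM in wild type and 137 ± 28.3 in knockout. The summed RPKM of the list was 2410 in knockout library 6, 508 and 546 in the other 2 knockout libraries, 269 to 471 in heterozygous and 245 to 358 in wild-type libraries. The summed level differed by log2 1.48 between knockout and wild type (exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.556). Without knockout library 6 the difference was 0.75 (exact permutation p = 0.0667, the smallest possible), the camera adjusted p was 2.84e-05 (median 0.97; adjusted p = 0.901 with an estimated correlation) and 4 members rose when adjusted over the list alone; Ngp, Camp, S100a9 and S100a8 then stood at log2 1.12, 1.15, 0.85 and 0.60. Monocyte markers followed (11 of 11 positive, median 0.74; camera adjusted p = 1.71e-07, and adjusted p = 0.631 with an estimated correlation), and 6 of 11 rose when adjusted over the list alone, among them Plac8 (log2 1.24) and Ly6c2 (0.98, and 0.33 without knockout library 6). Their sum was 154 in knockout library 6 and 43 to 61.1 in the other 9 libraries. Without knockout library 6 or wild-type library 1, 0 monocyte markers passed over the list alone, and 3 did without wild-type library 10. Likewise 0 passed without the sex term or without the filter on low values, and 4 with the CPM filter. The monocyte list had a median of 0.41 and an adjusted p of 0.0219 without knockout library 6 (adjusted p = 0.901 with an estimated correlation). T and NK cell markers were lower (3 of 3 negative, median -0.48; camera adjusted p = 0.0497, and adjusted p = 0.631 with an estimated correlation), all at levels under 1 RPKM. That call ended when any 1 library other than wild-type 4 or knockout 9 was left out (adjusted p from 0.0517 to 0.389), with a median of -0.17 without knockout library 6 and -0.27 without wild-type library 7 or 10, against -0.77 without wild-type library 4. It also ended with 6 other settings (adjusted p from 0.087 to 0.465), where the median ranged from -1.192 by limma-voom with the depth covariate to -0.029 without the filter.

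Markers of other brain cell types had smaller list medians in the knockout. They were -0.03 for astrocyte (Slc1a3 log2 0.03), 0.03 for oligodendrocyte (Cnp 0.03), 0.08 for endothelial (Slco1a4 -0.02), -0.06 for mural (Rgs5 -0.06), 0.17 for border macrophage (Mrc1 0.21) and 0.21 for choroid plexus and ependymal markers (Ttr 0.32), and none was called with all 10 libraries. Without knockout library 6, border macrophage markers were called higher (median 0.37; camera adjusted p = 0.0249, and adjusted p = 0.901 with an estimated correlation) and the endothelial median turned to -0.18 (adjusted p = 0.231). Endothelial markers were called higher without wild-type library 7 or knockout library 9 or 12 and with the depth covariate (adjusted p from 0.00565 to 0.0495). Choroid plexus and ependymal markers were called higher without wild-type library 1 (0.0267) or heterozygous library 5 (0.041). With the depth covariate astrocyte markers were called lower (0.0484, and 0.0167 by limma-voom), as were mural markers by limma-voom (0.0364). Lists with fewer than 3 measured genes were compared by their sums in knockout and wild type: 5.11 ± 0.998 and 5.51 ± 0.996 RPKM for neuron, 1.98 ± 0.496 and 2.04 ± 0.558 for oligodendrocyte precursor, 6.68 ± 1.59 and 8.27 ± 2.23 for B cell and 0.94 ± 0.403 and 0.488 ± 0.328 for erythroid markers. Exact permutation p-values for these 4 sums ran from 0.171 for erythroid to 0.943 for oligodendrocyte precursor markers. Mitochondrially encoded genes were not analysed here.

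Within the sets of lower and higher depth, some of these lists went in opposite directions. Each set held 1 library of 1 of the 2 genotypes, so these p-values concern the libraries compared. In libraries 1 to 8, where knockout library 6 was compared with 3 wild-type libraries, limma called 6 genes. Trem2 fell (log2 -2.735, limma adjusted p = 0.0381), and the neutrophil genes Camp, Ngp, Retnlg and S100a8 rose together with Ifitm6. In libraries 9 to 12, where both knockout libraries were male and the wild-type library female, Trem2 fell (log2 -2.917, limma adjusted p = 0.00218) and the other 5 called genes were the sex-linked Xist, Ddx3y, Uty, Kdm5d and Eif2s3y. Neutrophil markers were called higher in the shallower and the deeper set (medians 3.79 and 0.71; camera adjusted p = 1.75e-35 and 7.5e-16). Called lower in both were disease-associated genes (medians -0.165 and -0.29; 0.00175 and 2.51e-10), inflammatory genes (-0.26 and -0.22; 0.0417 and 4.54e-06) and lysosomal genes (-0.13 and -0.074; 0.0058 and 0.0409). Cell cycle and interferon-stimulated genes were called higher in libraries 1 to 8 (medians 0.76 and 0.54; 7.86e-10 and 3.31e-13) and lower in libraries 9 to 12 (-0.28 and -0.51; 0.0148 and 1.98e-18). Monocyte markers were not called in libraries 9 to 12 (0.322), T and NK cell markers not in libraries 1 to 8 (0.118), and survival genes in neither (0.515 and 0.051). Of the lists not called with all 10 libraries, endothelial markers were called higher in both sets (medians 0.415 and 0.39; 1.02e-06 and 3.23e-08) and border macrophage markers lower in libraries 1 to 8 (-0.35; 0.00346). With an estimated correlation none of these list calls held (lowest adjusted p = 0.617).

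**Figure D4:**
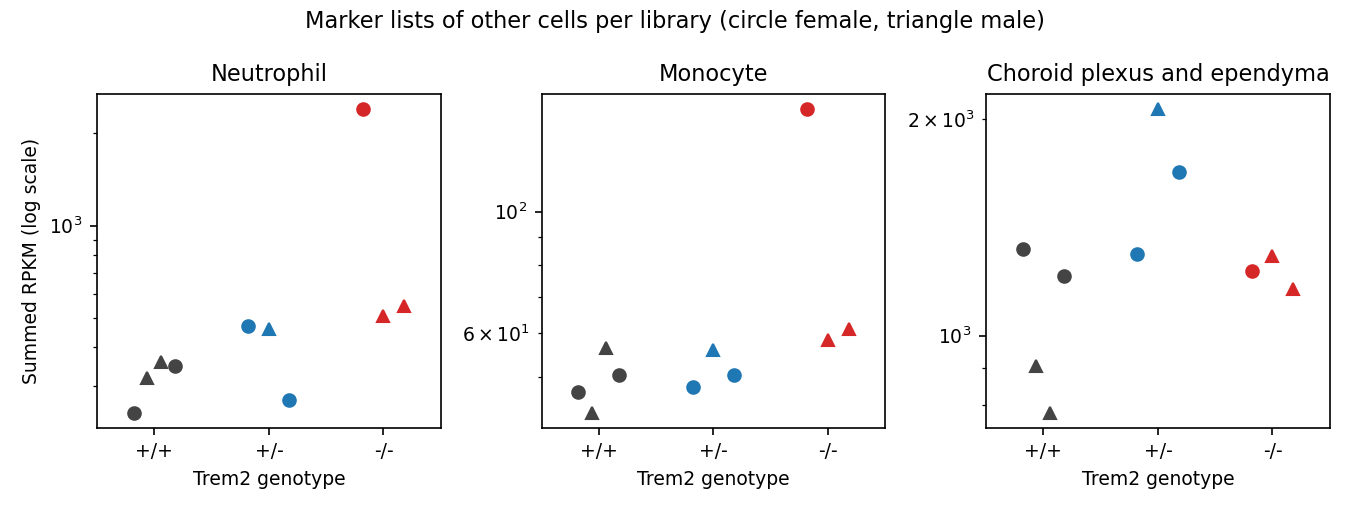
Summed RPKM (log scale) of neutrophil, monocyte and choroid plexus and ependymal markers in each library by Trem2 genotype; circles are female and triangles male libraries. Knockout library 6 stands at 2410 for neutrophil and 154 for monocyte markers, and the heterozygous libraries span 1300 to 2070 for choroid plexus and ependymal markers.

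Heterozygous against wild type addresses whether 1 copy of Trem2 is enough. Trem2 stood at 49.2% of wild type, and no gene passed in the model over all genes: limma called 0 of 13641, with 375 at an unadjusted p under 0.05 where 682 are expected by chance. Trem2 had the smallest p (log2 -1.02, SE 0.14, limma adjusted p = 0.239). It was the 1 gene that fell by limma-voom (adjusted p = 0.034) and by limma-voom with sample quality weights (adjusted p = 0.0138), and over all alternatives its adjusted p ran from 0.0138 to 1. Among the genes that the naming rule admits, the next smallest p-values were those of Scarna3a, a small Cajal body RNA (36.0 ± 9.86 RPKM in wild type, 20.1 ± 3.54 in heterozygous; log2 -0.72, SE 0.17), Treml2 (52% of wild type; log2 -0.89, SE 0.24), Car15, a carbonic anhydrase (log2 -0.70, SE 0.19), and Exd2, an exonuclease (14.5 ± 0.667 RPKM in wild type, 19.9 ± 2.29 in heterozygous; log2 0.43, SE 0.12), each with a limma adjusted p of 1. Of the 10 measured TREM cluster genes, 0 passed over all genes, 3 had an unadjusted p under 0.05 and 1 fell when adjusted over the list alone, Treml2 (limma adjusted p = 0.0367 over the list). That call ended without any 1 of wild-type libraries 4, 7 and 10, heterozygous libraries 5, 8 and 11 and knockout library 9, and without the filter on low values. By limma-voom Unc5cl rose over the list alone as well. Mdfi stood at 54.2% and Unc5cl at 271% of wild type, and the list had a median of 0.14. Within 1 Mb of Trem2, 3 of 27 other genes had an unadjusted p under 0.05 in heterozygous libraries. The share was 11.1% against 2.71% elsewhere (Fisher's exact test, p = 0.0364), with a rule and window chosen after the values had been seen. Of 35 splits of the wild-type and heterozygous libraries, 5 gave as many, so chance was not excluded.

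Of the gene lists, 4 were called in heterozygous libraries. Choroid plexus and ependymal markers were higher (8 of 8 positive, median 0.49; camera adjusted p = 9.5e-07, and adjusted p = 0.631 with an estimated correlation). Ttr, which carries thyroid hormone in cerebrospinal fluid, stood at 813 ± 205 RPKM in wild type and 1351 ± 330 in heterozygous libraries (log2 0.72, SE 0.21) and rose when adjusted over the list alone. That call of Ttr ended without any 1 of wild-type libraries 4 and 7, heterozygous libraries 8 and 11 and knockout libraries 6, 9 and 12, without the filter on low values or with the depth covariate. In contrast, 3 members passed by limma-voom or without wild-type library 1 and 7 without heterozygous library 5. Border macrophage markers were higher (10 of 10 positive, median 0.26; camera adjusted p = 0.00354, and adjusted p = 0.823 with an estimated correlation), with the hyaluronan receptor Lyve1 at log2 0.73 (SE 0.21). Immediate early genes, which respond to stimulation and to tissue dissociation, were also higher (24 of 28 positive, median 0.10; camera adjusted p = 0.0262, and adjusted p = 0.835 with an estimated correlation), with Zfp36 at log2 0.25 and Egr1 at 0.12. Interferon-stimulated genes were lower (27 of 32 negative, median -0.13; camera adjusted p = 0.00187, and adjusted p = 0.823 with an estimated correlation), although Ifitm3, the most abundant, was at log2 0.36. The choroid plexus and ependymal median was 0.81 without heterozygous library 5 and 0.22 without heterozygous library 8. The border macrophage call ended without wild-type library 4, heterozygous 5 or heterozygous 8 (adjusted p = 0.177, 0.0602 and 0.362) and with sample quality weights (0.116, median 0.081). Its median was 0.075 without wild-type library 4 and 0.054 without heterozygous library 8, against 0.41, 0.42 and 0.47 without wild-type libraries 1 and 10 and heterozygous library 11. The immediate early call ended without wild-type libraries 4 or 7, heterozygous 5 or 8, or knockout 6 (adjusted p from 0.0878 to 0.761; median -0.022 without heterozygous library 8), without the sex term (0.13) and without the filter (0.131). The interferon call ended without wild-type library 10 (0.287), heterozygous library 11 (0.244) or the sex term (0.195, median -0.073). The immediate early median was 0.06, 0.17 and 0.22 without wild-type libraries 4 and 10 and heterozygous library 11, and the interferon median -0.20 and -0.28 without wild-type library 1 and heterozygous library 8. The 26 uncalled lists had medians from -0.05 to 0.41, with homeostatic microglial genes at -0.04, disease-associated genes at -0.05 and neutrophil markers at 0.41 (camera adjusted p = 0.0551).

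Other lists were called in heterozygous libraries under some settings. Without knockout library 6, which enters the shared estimate of spread and of the sex effect, the neutrophil list was called in heterozygous libraries as well (median 0.54, camera adjusted p = 3.95e-05, and adjusted p = 0.901 with an estimated correlation). That list was also called without wild-type library 4 or 7, heterozygous 11, or knockout 9 or 12, without the sex term, with sample quality weights, with a pseudocount of 0.1 and with the depth covariate (adjusted p from 0.000214 to 0.0466). Astrocyte markers were called higher without wild-type library 7 or 10 or heterozygous 5 or 8 and by limma-voom (adjusted p from 0.00191 to 0.0329). Inflammatory genes were called lower without wild-type library 4 or heterozygous 8, with sample quality weights, and by limma-voom with the depth covariate (from 0.000484 to 0.0234). Endothelial markers were called lower without wild-type library 10 (0.0315) and homeostatic genes without wild-type library 1 (0.0491). Mural markers were called higher without heterozygous library 5 (0.00222), and disease-associated genes lower by limma-voom with the depth covariate (0.0439). Within libraries 1 to 8 (2 heterozygous, 3 wild type) and 9 to 12 (1 of each), limma called 0 genes, with 406 and 386 at an unadjusted p under 0.05. In libraries 1 to 8, choroid plexus and ependymal (median 0.45; camera adjusted p = 0.00064), border macrophage, immediate early and neutrophil lists were called higher (medians 0.53, 0.25 and 1; 4.08e-07, 1.81e-08 and 4.62e-13), and interferon genes were not called (-0.009; 0.75). With an estimated correlation none of these calls held (lowest adjusted p = 0.617). Between the single heterozygous and the single wild-type library of the deeper set, the medians of these 5 lists were 0.52, -0.30, -0.26, -0.47 and -0.39, values of 1 pair of libraries that do not test the genotype. With all 10 libraries and an estimated correlation, camera called 0 lists (1 at an unadjusted p under 0.05), and fry called 0 (lowest adjusted p = 0.798, with 0 lists at an unadjusted p under 0.05). The sign of the median differed from the camera direction in 2 lists and that of the mean in 4, none of them called.

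Knockout against heterozygous compares loss of the last copy. Trem2 was the 1 gene of 13641 that changed by limma, 0 genes rose, and 458 genes had an unadjusted p under 0.05 (301 higher, 157 lower), where 682 are expected by chance. limma-voom also called Trem2 alone, and with the deeper libraries as a covariate it called 3 genes (Trem2, Camp and Ltf). B430306N03Rik, whose clone name the naming rule leaves out, had the next smallest p (log2 0.87, SE 0.15, limma adjusted p = 0.78). Among the genes that the rule admits, it was followed by Ddit4, a stress-induced inhibitor of mTORC1 (8.21 ± 2.51 RPKM in heterozygous, 2.88 ± 0.81 in knockout; log2 -1.26, SE 0.27), and Rcan1, a regulator of calcineurin (log2 -0.72, SE 0.17). Polr3d, a subunit of RNA polymerase III (log2 0.85, SE 0.19), Asf1a, a histone chaperone (log2 0.56, SE 0.13), and Fbxo5, an inhibitor of the anaphase-promoting complex (log2 1.36, SE 0.32), were on the higher side. None of these 5 passed (limma adjusted p = 0.999 for each). In the TREM cluster 0 genes passed over all genes or over the list alone by limma, and 4 had an unadjusted p under 0.05.

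The lists called in knockout against heterozygous numbered 10, and 0 were called without knockout library 6 (adjusted p from 0.231 to 0.591), against 6 without heterozygous library 8. The medians without knockout library 6 were 0.30 for neutrophil, 0.18 for monocyte, 0.093 for interferon and 0.14 for cell cycle lists. They were -0.016 for immediate early, -0.014 for disease-associated, -0.024 for inflammatory, -0.14 for astrocyte and -0.31 for choroid plexus lists, and 0.19 for border macrophage markers, which turned. Higher in the knockout were neutrophil markers (median 1.38; camera adjusted p = 1.09e-09, and adjusted p = 0.631 with an estimated correlation), interferon-stimulated genes (30 of 32 positive, median 0.23; camera adjusted p = 3.03e-08, and adjusted p = 0.631 with an estimated correlation), cell cycle genes (22 of 24 positive, median 0.29; camera adjusted p = 3.94e-05, and adjusted p = 0.631 with an estimated correlation) and monocyte markers (median 0.41; camera adjusted p = 5.59e-05, and adjusted p = 0.631 with an estimated correlation). Adjusted over the list alone, 3 neutrophil genes (Mmp9, Camp and Ngp) and 1 monocyte gene (Plac8) rose. For neutrophil genes the count was 0 without heterozygous library 5 or 11 or knockout library 6, and 8 or 9 without wild-type library 1, heterozygous library 8 or knockout library 9 or 12. Plac8 lost its call without wild-type library 7 or 10, heterozygous library 8 or 11, or knockout library 6 or 9, while 3 monocyte genes passed without knockout library 12. Without the filter on low values 0 genes of either list passed, while 8 neutrophil genes did by limma-voom or with the CPM filter and 9 with the depth covariate. Plac8 also lost its call without the sex term, with sample quality weights or with the CPM filter, while 3 monocyte genes passed by limma-voom and 5 with the depth covariate. Lower were immediate early genes (24 of 28 negative, median -0.15; camera adjusted p = 1.26e-05, and adjusted p = 0.755 with an estimated correlation), with the phosphatase Dusp1 at log2 -0.38, and disease-associated genes (23 of 28 negative, median -0.13; camera adjusted p = 0.00036, and adjusted p = 0.694 with an estimated correlation), with Lpl at log2 -0.46. Also lower were choroid plexus and ependymal markers (median -0.36; camera adjusted p = 0.00636, and adjusted p = 0.78 with an estimated correlation) and inflammatory and NF-kB genes (median -0.06; camera adjusted p = 0.0265, and adjusted p = 0.823 with an estimated correlation), as were border macrophage markers (median -0.13; camera adjusted p = 0.0265, and adjusted p = 0.835 with an estimated correlation) and astrocyte markers (median -0.22; camera adjusted p = 0.0497, and adjusted p = 0.835 with an estimated correlation).

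Several of these 10 calls ended under single settings or without single libraries. Without heterozygous library 8, the calls of immediate early (adjusted p = 0.108), choroid plexus (0.8), inflammatory (0.875) and border macrophage genes (0.713) ended. There the inflammatory list turned to the higher side, and the choroid plexus and border macrophage medians turned to 0.067 and 0.036. Disease-associated and immediate early medians were -0.082 and -0.014 there, and that of monocyte markers 1.02. Without heterozygous library 11 the astrocyte median turned to 0.075, and those of border macrophage, immediate early and inflammatory lists were -0.24, -0.23 and -0.12. The same 3 were -0.29, -0.265 and -0.13 without knockout library 12. Without heterozygous library 5, medians were -0.45 for astrocyte, -0.59 for choroid plexus and -0.10 for inflammatory lists. Further calls ended without wild-type library 1 (astrocyte, 0.0745), wild-type 7 (astrocyte, 0.1), heterozygous 5 (border macrophage, 0.167, and inflammatory, 0.0617), heterozygous 11 (astrocyte, 0.825, and choroid plexus, 0.0853), knockout 9 (astrocyte, 0.0973) or knockout 12 (inflammatory, 0.0619). The inflammatory call also ended without the sex term (0.0571), by limma-voom (0.0556) and without the filter (0.147). The border macrophage call ended by limma-voom (0.146, or 0.0864 with the depth covariate), with sample quality weights (0.0707) and without the filter (0.0931). The astrocyte call ended without the filter (0.245), with the CPM filter (0.114), with a pseudocount of 0.1 (0.0528) and with median-ratio scaling (0.0644). Of the uncalled lists, autophagy genes were called lower under 6 settings (adjusted p from 0.0158 to 0.0389) and endothelial markers higher under 6 (0.0128 to 0.0356). Lysosomal genes were called lower under 4 settings (0.00861 to 0.0289), mural markers lower under 3 (0.00113 to 0.0319) and ribosomal genes lower without knockout library 9 (0.022). TREM cluster genes were called higher by limma-voom with the depth covariate (0.0373). Within libraries 1 to 8, where knockout library 6 was compared with 2 heterozygous libraries, limma called Ngp alone (Trem2 log2 -1.70, limma adjusted p = 0.395). Within libraries 9 to 12, where sex again followed the knockout, it called Trem2 and the same 5 sex-linked genes. Each set again held 1 library of 1 of the 2 genotypes. Neutrophil (medians 2.74 and 1.31) and monocyte lists (0.80 and 0.31) were called higher and disease-associated genes lower (-0.21 and -0.13) in both sets. Border macrophage (-0.83 and 0.45) and immediate early lists (-0.50 and 0.23) were called in opposite directions, and the other 5 lists were called in 1 set each. With an estimated correlation none of these calls held (adjusted p of at least 0.617). With all 10 libraries, the 20 uncalled lists had medians from -0.32 to 0.31. The sign of the median differed from the camera direction in 5 lists and that of the mean in 6, none of them called, and fry called 0 lists (lowest adjusted p = 0.798).

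Across the series of 2, 1 and 0 copies, Trem2 was the 1 gene whose level changed with each lost copy by limma (log2 -1.44 per copy, SE 0.10, adjusted p = 5.37e-05), and 741 genes had an unadjusted p under 0.05. The count was 2 by limma-voom (with Treml2) and 3 without knockout library 6 (with Treml2 and Mir5104). Against the midpoint of wild type and knockout on the log scale, limma called 0 genes in heterozygous libraries. At an unadjusted p under 0.05 there were 341 genes, and limma-voom also called 0. Trem2 lay 0.44 above that log-scale midpoint (SE 0.13, limma adjusted p = 0.999). On the RPKM scale its heterozygous level (93.9) lay below the midpoint of wild type (191) and knockout (24.5).

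Fold changes of heterozygous and knockout against wild type were compared across 13640 genes, which are not independent replicates. They correlated with Pearson's r = 0.446 and Spearman's rho = 0.437, with a covariance of 0.0269. Because both comparisons use the same 4 wild-type libraries, unchanged groups were simulated against them, which gave r = 0.402 (range 0.366 to 0.431) and a covariance of 0.0208 (range 0.0184 to 0.0231). The observed r and covariance lay above all 100 simulated values. The simulation drew each gene independently, whereas real genes vary together. Its range is therefore too narrow to test for a response shared by the 2 genotypes. With the wild-type libraries split so that no control was shared, which leaves 2 controls per fold change and was done without the sex term, r averaged 0.014 over 6 splits (range -0.152 to 0.0838). No gene was called in both comparisons. Leaving out 1 library moved r from 0.26 without heterozygous library 8 to 0.548 without wild-type library 10.

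Sex, a term in the fits except where stated, served to check the labels. Xist, the RNA that coats the inactive X chromosome, stood at 338 ± 48.9 RPKM in the 5 female and 0.67 ± 0.265 in the 5 male libraries (log2 -8.14, limma adjusted p = 1.96e-10). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were higher in males by log2 5.63, 4.18, 4.34 and 5.76, and all 10 libraries matched their labelled sex. Pcp4, a calmodulin-binding peptide, was the 1 other gene that changed with sex (6.96 ± 0.929 RPKM in females, 11.4 ± 0.994 in males; log2 0.72, limma adjusted p = 0.0365).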

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

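The tests of a sex difference in the genotype effect and those of the neutrophil pattern, counts of splits included, were chosen after the results had been seen. Of 35 sets of 4 wild-type values examined for a value far from the other 3, 2 held one, and chance gives about 1 in 20. Car15 stood at 5.56 RPKM in wild-type library 4 against 3.25 to 3.63 in the other 3 wild-type libraries. Recovered reads numbered 44.3 M in wild-type library 10 against 18.1 M to 22.1 M in the other 3.

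In a fit with a genotype-by-sex term, the knockout effect differed between males and females for 2 genes (2027 at an unadjusted p under 0.05) and the heterozygous effect for 1 gene (1429). Mmp8, a neutrophil collagenase, had a knockout effect lower in males by a log2 difference of -4.28 (limma adjusted p = 0.0408), with 40.4 RPKM in knockout library 6, 6.61 and 3.8 in knockout libraries 9 and 12, and 2.08 to 7.31 in wild type. S100a11, a calcium-binding protein, had a difference of -2.24 (limma adjusted p = 0.0408), with 56.3 RPKM in knockout library 6 and 11.4 to 22.2 in the other 9 libraries. The microRNA gene Mir467f had a heterozygous effect lower in males by -2.96 (limma adjusted p = 0.0101), with 29.9 and 38.7 RPKM in the male wild-type libraries and 2.31 in heterozygous library 8. Knockout library 6 was the 1 female knockout library and heterozygous library 8 the 1 male heterozygous library, so each difference rests on 1 library, with 4 residual degrees of freedom.

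Neutrophil markers were higher in the knockout list by a camera -log10 p of 14.2, and 1 of the 35 splits of the 7 wild-type and knockout libraries, the real one, gave a value as large, against a highest other of 10.281. That other split kept the 3 knockout libraries together with wild-type library 7, so the list value there in part carries the genotype contrast. Because that list was singled out for its value, the largest value among the 30 lists was counted as well, and 1 of 35 splits, the real one, reached 14.2 (highest other 11.343); 1 of 35 is the smallest share possible and the comparison was picked after its values were seen, so chance stays open. Knockout library 6 held the highest level of 10 of the 11 measured markers, with S100a9 at 1040 and S100a8 at 479 RPKM against wild-type means of 67.2 and 53.5, which is consistent with neutrophils carried over in that library; CD11b beads would retain such cells, and Csf3r, which these microglial libraries also hold, was at 108 RPKM there against a wild-type mean of 132. Whether library 6 accounts for the whole pattern cannot be told apart from a difference in all 3 knockout libraries, since without it camera gave an adjusted p of 2.84e-05 with the preset and 0.901 with an estimated correlation, and in libraries 9 to 12, with a median of 0.711, knockout and sex were not separable. A difference in neutrophil numbers between genotypes or sexes was not tested and stays open.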

How the results depend on the processing

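Most alternatives were fixed before the values were seen; the pseudocounts, median-ratio scaling, the depth covariate, the fits within each depth set, list tests under limma-voom and other filters, the unadjusted counts near Trem2 and the marker sums with 1 library left out were added later. Trem2 fell in knockout against wild type under every alternative run, and against heterozygous under every one except libraries 1 to 8 alone (log2 -1.699, limma adjusted p = 0.395). The planned edgeR test and the planned fits with DESeq2 size factors and with the DESeq2 Wald test were not run. The deposited values are RPKM, but the recovered whole reads would have allowed these tests. limma-voom, without and with sample quality weights, called 2 and 2 genes in knockout against wild type, 1 and 1 in heterozygous against wild type (Trem2 at log2 -1.003 and -0.997) and 2 and 2 per copy. The depth covariate gave 2 genes in knockout against wild type; with limma-voom it gave 17 genes in knockout against wild type, 3 in knockout against heterozygous and 16 per copy, and 8 lists in heterozygous against wild type. Libraries 1 to 8 alone gave 6 genes in knockout against wild type; libraries 9 to 12 alone gave 6 there and 6 in knockout against heterozygous, 5 of each sex-linked, and 14 lists in heterozygous against wild type, where 1 library was compared with 1. Camera with an estimated correlation and fry called 0 and 0 lists in knockout against wild type, 0 and 0 in heterozygous against wild type and 0 and 0 in knockout against heterozygous. The correlation of heterozygous and knockout fold changes was 0.493 at an average log2 CPM of at least 3 and 0.0144 with no shared control, which also left 2 controls per fold change and no sex term; unchanged groups with shared controls gave 0.402. Of 840 values of named genes other than Trem2, 808 kept direction and side of the threshold, 6 newly passed it (Treml2 under 4 settings, Mmp9 and Unc5cl with limma-voom and the depth covariate) and 26 turned, in 10 results. Trem1 in heterozygous against wild type turned to 0.079 without the sex term, 0.082 with 2 genotypes in the fit and 0.035 with the depth covariate; Foxp4 turned to 0.029 in knockout against wild type (limma-voom) and -0.018 in heterozygous against wild type (sample quality weights), and Oard1 to 0.02 in knockout against heterozygous (limma-voom with the depth covariate). Leaving out 1 library at a time gave 1 to 3 genes in knockout against wild type and 1 to 3 per copy, 3 to 10 lists in knockout against wild type and 0 to 13 in knockout against heterozygous, and a correlation of 0.26 to 0.548. The log2 difference ranged from 0.746 to 1.866 for neutrophil and from 0.282 to 0.974 for monocyte marker sums, where the exact permutation test cannot go below 0.0667 or 0.1. Ranges in knockout against wild type were -0.267 to 0.277 for Foxp4, -0.038 to 0.155 for Oard1 and 0.002 to 0.176 for the interferon list. In heterozygous against wild type they were -0.526 to 0.367 for Trem1, -0.029 to 0.454 for Treml1, -0.049 to 0.342 for Foxp4, -0.054 to 0.235 for Nfya, -0.018 to 0.294 for Oard1, and 2.07% to 7.59% for genes within 10 Mb of Trem2 with an unadjusted p under 0.05 (4.14% without heterozygous library 11). In knockout against heterozygous they were 0 to 1.476 for Trem1, -0.335 to 0.182 for Foxp4, -0.207 to 0.113 for Oard1, and in list medians -0.294 to 0.189 for border macrophage, -0.134 to 0.087 for inflammatory, -0.592 to 0.067 for choroid plexus and ependymal and -0.446 to 0.075 for astrocyte lists. Of the 9 lists called in knockout against wild type, 2 were still called without knockout library 6, 6 with limma-voom or without the filter, 8 without the sex term and 9 with a pseudocount of 1. Without the sex term 2 of 4 were still called in heterozygous against wild type and 9 of 10 in knockout against heterozygous. Apart from the fits with fewer libraries, the cause was not tested. Fold changes of 1.5 were recovered in 0% to 22.8% of simulated genes, with about 200 genes changed at once. Such shares do not carry over to data in which few genes change. There Trem2 in heterozygous against wild type (log2 -1.02) had a limma adjusted p of 0.239. Changes of 1.5-fold, and larger ones, may therefore have been missed.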

Other observations

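Tests of knockout library 6, of flanking DNA, of microglial RNA content and of depth were chosen after the results had been seen, as were the patterns they concern and the split counts for those patterns; counting other splits for numbers of genes and lists was fixed earlier. Some members of uncalled lists had an unadjusted p under 0.05 in the knockout, and none passed over its list alone. Among complement and cholesterol genes, C3, the central complement component, was at 2.54 ± 1.13 RPKM in wild type and 6.13 ± 5.69 in knockout (log2 1.01, SE 0.32), with 12.7 in knockout library 6 and 2.83 and 2.87 in the other 2 (log2 0.42 without library 6, unadjusted p = 0.147). Ebp, a sterol isomerase, was at 5.90 ± 0.419 and 8.36 ± 1.35 (log2 0.50, SE 0.14) and Msmo1 at log2 0.28 (SE 0.12). Ldha, the lactate dehydrogenase of glycolysis, was at 43.7 ± 7.04 and 52.4 ± 4.54 RPKM (log2 0.29, SE 0.13).

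Genes near Trem2 differed in the knockout in both directions. Within 1 Mb 12 of 27 genes, 7 of them members of the TREM cluster list, had an unadjusted p under 0.05. This rule and window were chosen after the values had been seen. By that rule 1 of 35 splits of the wild-type and knockout libraries, the real one, gave as many. The highest other, 8, came from splits that kept the 3 knockout libraries together with 1 wild-type library. Within the planned 10 Mb, 3 of 35 gave at least the 24 genes seen (highest other 32), so chance was not excluded there and stays open for the narrower window. Without knockout library 6 the share within 1 Mb was 29.6% (Fisher's exact test, p = 0.000197). That test treats neighbouring genes as independent, and no splits were counted without library 6. It therefore cannot decide whether library 6 alone accounts for the raised share. Treml2 still fell without that library (log2 -1.954). Flanking DNA carried with the targeted allele may contribute, but 10.2% of genes from 1 to 10 Mb had such a p (Fisher's exact test, p = 0.0182) and 7 of 35 splits gave as many there (12 genes, highest other 30), so this explanation and an effect of the allele on its neighbours cannot be told apart. In heterozygous libraries 5 of 35 splits gave as many as the 3 genes seen (highest other 6), so chance was not excluded.

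Lower disease-associated genes in the knockout (camera -log10 p of 5.986) were matched in 3 of 35 splits, with a highest other of 7.171, so chance was not excluded. Less microglial RNA in the knockout libraries was examined through homeostatic genes, at a median of 0.028 (SE 0.0292) against -0.132 (SE 0.0726) for the list. The gap was narrowly beyond the limit of 2 standard errors that was set. Those errors treat list members as independent, although the estimated correlations between members were 0.179 and 0.221. The limit therefore cannot decide, and this explanation stays open. By camera at the preset correlation, the call held with the depth covariate (adjusted p = 3.45e-08). This argues against sequencing depth as the source of that call only. With an estimated correlation, camera called no list under that covariate (lowest adjusted p = 0.424). Knockout library 6 alone remains a candidate explanation, since the adjusted p was 0.141 without it, although the median was still -0.08 there and was -0.287 in libraries 9 to 12, where knockout and sex were not separable. An effect of Trem2 loss stays open.

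Other splits of the libraries also gave results as large for most counts. In knockout against wild type, 4 of 35 splits gave as many genes as the 1 seen (highest other 1) and 7 of 35 as many lists as the 9 seen (highest other 12). In heterozygous against wild type 28 of 35 gave at least the 4 lists seen (highest other 12), so chance was excluded in none of these counts. With 0 genes called in heterozygous against wild type (highest other 8) and 0 against the midpoint (highest other 17), 35 of 35 splits and 100 of 100 regroupings reached that value by construction, which tests nothing. In knockout against heterozygous, 10 splits are too few for a share under 0.05; the real values were 1 gene (highest other 0, with 1 split as large) and 11 lists adjusted within that comparison (highest other 11, with 2 splits as large). Per Trem2 copy, 6 of 100 regroupings gave at least the 1 gene seen, so chance was not excluded for that number; these counts take no account of which gene was called, and the 1 gene seen was Trem2, whose 3 genotypes did not overlap. Of the other 99, 94 called 0 genes and the highest called 402, far above the real count. That regrouping placed wild-type library 4, heterozygous 5 and knockout 6 together in the group labelled knockout. Their library totals were 1.0231, 1.0258 and 1.0262 times the recovered reads, against 1.0176 to 1.0196 in the remaining libraries. This may point to a structure of the samples that sets these libraries, whose label numbers are consecutive, apart. Its cause was not tested, and it was not a term in any fit.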
